A study of Mus musculus with 2 samples.

How the data were processed

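The data were DNase-seq libraries from the right cerebral cortex of male B6CASTF1/J mice aged 10 days, 1 group of 2 biological replicates. Per the labels, the tissues came from separately numbered animals, while both carry the same donor identifier, so how far the spread between them is that between animals is not certain. No further group existed and no comparison between groups was made. Values are given per library or as mean and SD (n = 2), and no p-values were computed, because genes, peaks and motif sites are not replicates.

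Per the deposited file lists, the authors derived peaks, footprints and base-level rates of each library from its own filtered alignments on mm10, and libraries were not pooled. The aligner, the peak and footprint callers, their versions and the filters are not given in the sources used here. For each library the authors deposited 2 peak files whose signal, the peak height, is a whole multiple of 1 step per library, as the values show. The constant behind this step is not stated, and depth is therefore treated as unknown. The authors deposited p-value-like false discovery rates (FDR) of the local cut rate, per the deposited file lists, and these listed only values below 0.05. Tested against these rates, every peak of 1 deposited file touched bases with FDR at or below 0.001 and every peak of the other touched bases at or below 0.05. The file covering less of the genome, that at 0.001, was the main peak set. The plan had called it the narrower file, and this was taken to mean the one covering less. Footprint files of the authors hold 1 constant score, so only footprint positions were used. Peak files give no summit position, and peak centres were used.

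Replicates were compared by overlap of at least 1 bp, beside 100 circular shifts. Peaks were placed by centre on the GENCODE vM21 basic annotation of GRCm38 as promoter (within 1 kb of a transcription start), exon, intron or intergenic. For 31 gene lists and 4 gene families the number of genes with a promoter peak in both libraries was ranked among 10000 random lists drawn from protein-coding genes. The lists were excitatory neurons, upper and deep cortical layers, inhibitory neurons, synaptic proteins, immediate early genes, astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, microglia, endothelial cells, pericytes and smooth muscle, choroid plexus and ependyma, neural progenitors, cerebellum, striatum, monoaminergic neurons, thalamus and hypothalamus, retina, Hox genes, hepatocytes, skeletal muscle, heart, keratinocytes, erythroid cells, lymphocytes, intestine, pancreas, germ line, imprinted genes and housekeeping genes. The families were olfactory receptors, vomeronasal receptors, keratin-associated proteins and clustered protocadherins. A list was called above or below at percentiles of at least 97.5 or at most 2.5. Distal density was the number of peaks more than 1 kb from any start per 100 kb of gene body extended by 10 kb on each side, as the median over the list of each gene's mean over the libraries, ranked among 10000 random lists matched on deciles of locus length.

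For 30 motifs, the share of distal peaks with the consensus on either strand within 75 bp of the centre was divided by the mean over 20 column permutations of the same consensus. For footprints, the share of sites at least 50% covered was divided by that of permuted sites in the same peaks. A motif was called at 1.5-fold or more in both libraries, and a ratio needed at least 5 expected permuted hits. Confidence intervals are Wilson intervals at 95%, which cover counting error only.

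The lists, families, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes were up to 4 members per list with the highest mean promoter height and a peak in both libraries, up to 4 members in alphabetical order with none in either, the 10 protein-coding genes with the most shared distal regions, the 5 highest shared regions, and the 5 protein-coding genes per library with the highest promoter peak absent from the other. Some genes that this rule names are not reported here. Values beyond the rule, such as the distal densities at listed genes, were chosen after the values were seen. Alternatives were another promoter distance (500 bp, 2 kb), the higher 50% of peaks by height, the other peak file, reciprocal overlap, equal numbers of top peaks, other locus extents, CpG-matched random lists, flanking or narrower motif windows, other footprint cover, promoter or distal peaks alone on the X chromosome, and each library alone. Permutations keeping CpG steps and peak sets without dense runs of low peaks (at least 10 peaks of height below 0.3 within 25 kb on either side) were added after the data were seen.

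Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used. Tested on simulated data, overlaps of 20000 intervals differed from bedtools in 0 cases under 3 settings. Of 400 unplanted lists 3.5% passed the promoter limits. All 200 lists planted with few open genes passed the lower limit (100%), and lists planted with every gene open all passed the upper limit (100%). Each kind held a fixed number of open genes, so the 100% gives no recovery rate for other lists. For distal density 4% of unplanted lists and 87% of lists planted at 4-fold passed, over 21000 genes. Planted motif sites were found in 100% of 994 windows.

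Alleles of the CAST/EiJ parent were aligned to a reference of the other parent, and the effect of this on heights could not be tested here. Mappability was not measured, which limits statements on multi-copy families and on the Y chromosome.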

Results

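DNase-seq was carried out on the right cerebral cortex of male mice aged 10 days. In this assay the enzyme DNase I cuts nuclear DNA, and a stretch cut more often than its surroundings is called as a peak of accessible chromatin. The animals were B6CASTF1/J, the first-generation hybrid of the inbred strains C57BL/6J and CAST/EiJ. The series held 1 group of 2 libraries, biological replicates 1 and 2, so no treatment, age or tissue was contrasted and the labels state no question beyond the map itself. The questions addressed were how far the replicates shared their accessible regions, where those regions lay, which cell-type and tissue gene sets they marked, which transcription factor motifs they held, and how the sex chromosomes compared with the autosomes. Sequencing depth was not stated. Peak heights were whole multiples, within 0.05 of a step, of 0.00299 in replicate 1 and 0.00332 in replicate 2 for 100% of peaks, so the scale was set per library by a constant that is not stated. All coordinates are on mm10, and errors are SDs over the 2 libraries (n = 2).

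Replicate 1 had 127904 peaks over 26.1 Mb, which was 0.985% of the known bases, and replicate 2 had 135548 peaks over 25.1 Mb, or 0.949%. The mean was 131726 ± 5405 peaks (SD, n = 2). The median peak was 200 bp wide in replicate 1 and 180 bp in replicate 2. Median heights were 0.589 and 0.721 on the deposited scale.

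The replicates shared most of their high peaks and fewer of their low ones. Of the peaks of replicate 1, 65.3% met a peak of replicate 2 by at least 1 bp (Wilson 95% interval 65.1 to 65.6, counting error only), against a mean of 2.02% after 100 circular shifts along the chromosomes. For replicate 2 the share was 62.4% (62.1 to 62.7) against 1.92%. Shared peaks had a median height of 0.837 in replicate 1 and 1.02 in replicate 2, and peaks not shared had 0.245 and 0.438. Against the peaks of the other library at FDR 0.05, 76.4% of replicate 1 peaks and 77.4% of replicate 2 peaks were shared. Some peaks called in 1 library alone thus had a weaker peak in the other. Merging both sets gave 174519 regions, of which 81094 were present in both libraries, 43136 in replicate 1 alone and 50289 in replicate 2 alone. Across the 81094 shared regions, which are not independent replicates, heights correlated with a Spearman coefficient of 0.876 and a Pearson coefficient of 0.914 on the log2 scale. The median height ratio of replicate 2 to replicate 1 was 1.17.

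The 5 shared regions with the greatest mean height lay at promoters, inside genes and, in 1 case, between genes. The highest, chromosome 1 from 88277521 to 88277760, covered a promoter at Hjurp, which encodes a histone chaperone of the centromere, and overlapped the annotated gene Trpm8, and its height was 30.9 ± 5.56. A region on chromosome 15 from 99735661 to 99736060 in an exon of Cers5, a ceramide synthase gene, had a height of 27.2 ± 0.704. An intergenic region on the X chromosome from 143482981 to 143483140, 35451 bp from the nearest start of Pak3, had 12.1 in replicate 1 and 39.2 in replicate 2. A region in an intron of Mid1, X chromosome 169998241 to 169998420, had 25.3 ± 6.28. The promoter of Bahcc1 on chromosome 11, from 120232681 to 120232900 and 47 bp from its start, had 21.2 ± 0.713.

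Peaks were concentrated at gene starts. Promoters, defined as positions within 1 kb of an annotated transcription start, held 24.6% ± 1.38 of peak centres, against 4.41% of 263452 random positions. Exons outside promoters held 5.62% ± 0.0400 against 3.08% at random. Introns held 38.1% ± 1.42 against 42.4%, and intergenic sequence held 31.7% ± 0.00257 against 50.1%. Promoter peaks were also the highest, with a median of 1.11 ± 0.0714, compared with 0.592 ± 0.0975 in introns, 0.546 ± 0.0963 in exons and 0.534 ± 0.0620 between genes.

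Promoters of excitatory neuron and cortical layer genes were accessible in every member of their lists. A promoter is called open where both libraries had a peak within 1 kb of an annotated start, and the value given for a gene is the mean height of its strongest such peak. A peak near the starts of several genes counted for each of them, so such a peak need not belong to the named gene. All 12 genes of the excitatory neuron list had a promoter peak in both libraries, among them Camk2a (4.03 ± 0.405), which encodes a kinase of glutamatergic synapses, and the basic helix-loop-helix factors Neurod2 (3.24 ± 0.599) and Neurod6 (2.34 ± 0.188). The promoters of all 10 upper-layer genes were open, led by the POU factor genes Pou3f3 (9.03 ± 3.17) and Pou3f2 (4.56 ± 0.401), with Lhx2 at 3.44 ± 0.0865 and the layer 4 receptor gene Rorb at 2.96 ± 0.416. So were those of all 10 deep-layer genes, with the co-repressor gene Tle4 at 15.2 ± 4.87, Bcl11b, a regulator of subcerebral projection neurons, at 2.27 ± 0.138, Etv1 at 2.24 ± 0.0798 and Foxp2 at 2.21 ± 0.372. All 19 synaptic genes were open, including the scaffold genes Homer1 (7.09 ± 0.923) and Dlg4 (5.82 ± 0.456) and the calcium sensor gene Syt1 (4.87 ± 0.957). All 15 immediate early genes, which neuronal activity induces, were open, with Egr1 at 7.64 ± 0.341, Fosb at 6.13 ± 0.113, Arc at 5.80 ± 0.0380 and Dusp1 at 5.75 ± 0.134. Over all protein-coding genes 13580 of 21938, or 61.9%, had a promoter peak in both libraries.

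Set against 10000 random lists of protein-coding genes of equal size, the number of open promoters lay at percentile 99.8 for excitatory neurons, 99.6 for upper and for deep layers, 99.99 for synaptic proteins and 99.98 for immediate early genes, all past the upper limit. Drawn from genes of like CpG content, random lists left upper layers at 96.3 and immediate early genes at 90.4, inside the limits. The 15 housekeeping genes, such as Ywhaz (10.3 ± 0.102), Rpl13a (9.93 ± 1.77), Rplp0 (9.91 ± 1.73) and Tbp (8.17 ± 0.0324), were all open as well, at percentile 99.98.

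Interneuron genes lay inside the limits. Of 17 inhibitory neuron genes 13 had a promoter peak in both libraries, where 10.5 were expected (percentile 88.4). Among the highest were Adarb2 (1.41 ± 0.371), Dlx6 (1.35 ± 0.518) and Prox1 (1.33 ± 0.0658). Lhx6, a factor of interneurons from the medial ganglionic eminence, and Sst, which encodes the peptide somatostatin, had no promoter peak in either library. In replicate 1 alone 15 were open (98.6) and with peaks at FDR 0.05 it was 16 (99.4), both past the limit. The percentile was 53.8 against CpG-matched lists and 34.3 in the higher 50% of peaks, where 9 were open.

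Among glia, astrocyte genes were mostly open and most myelin genes were not. Of 14 astrocyte genes 12 had a promoter peak in both libraries (percentile 96.8), including Sox9 (4.02 ± 0.490), the glycolytic gene Aldoc (2.29 ± 0.275) and the glutamate transporter gene Slc1a2 (2.05 ± 0.0544), while Gfap, which encodes an intermediate filament, had none. The oligodendrocyte precursor list had 6 of 10 open (45.3), with the transcription factor genes Sox8 (3.38 ± 0.356), Olig1 (2.01 ± 0.567) and Olig2 (1.54 ± 0.0741) and the growth factor receptor gene Pdgfra (1.66 ± 0.762), and none at Bcas1 or Cspg4. Of 12 genes of myelinating oligodendrocytes 3 were open, Cnp (1.32 ± 0.290), Mbp (1.15 ± 0.264) and Ugt8a (0.75 ± 0.0892), at percentile 0.640 and so past the lower limit. Aspa, Ermn, Mag and Mobp, all genes of mature oligodendrocytes, had no promoter peak in either library. The astrocyte percentile passed the upper limit against CpG-matched lists (98.7), within 2 kb of a start (99.1), with peaks at FDR 0.05 (99.8; 14 of 14 open, Gfap included) and without replicate 1 (98.8), while in the higher 50% of peaks 7 of 14 were open (27.97) and within 500 bp of a start 11 (91.5). The myelin list came back inside the limits without replicate 1 (5 of 12, 4.99) and with peaks at FDR 0.05 (3.84).

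Vascular and immune cell genes gave intermediate counts. Microglial genes were open at 6 of 15 (percentile 4.68), with the complement gene C1qc at 1.57 ± 0.738, Sall1 at 1.27 ± 0.0167 and Tmem119 at 0.607 ± 0.0430, and none at Fcrls, Itgam and Trem2. Endothelial genes were open at 4 of 11 (4.89), namely the glucose transporter gene Slc2a1 (3.73 ± 0.745), the growth factor receptor genes Kdr (0.703 ± 0.264) and Flt1 (0.533 ± 0.153), and Abcb1a (0.344 ± 0.186), and had no peak at Cdh5, Tek and Tie1. Pericyte and smooth muscle genes were open at 6 of 9 (60.3), with Tagln at 1.47 ± 0.648, Notch3 at 1.31 ± 0.385, Pdgfrb at 1.07 ± 0.516 and Myh11 at 1.02 ± 0.592, and none at Abcc9 and Acta2. Choroid plexus and ependymal genes were open at 3 of 9 (5.03), led by the ciliary factor gene Foxj1 (6.47 ± 0.550), with Aqp1 at 0.616 ± 0.0214 and Prlr at 0.420 ± 0.0446, and none at Clic6, Folr1, Kcnj13 and Kl. The 3 lists other than pericytes were past the lower limit in the higher 50% of peaks, at percentiles of 0.305 for microglia, 0.065 for endothelium and 0.260 for choroid plexus. Microglia were also past it within 500 bp of a start (1.90), endothelium against CpG-matched lists (2.14) and choroid plexus with peaks at FDR 0.05 (2.44), whereas microglia against CpG-matched lists were at 60.0. Either library alone had more open promoters than both together for microglia, with 10 of 15 in replicate 1 (59.2) and 8 in replicate 2 (17.1), and for endothelium, with 5 of 11 in replicate 1 (12.5) and 7 in replicate 2 (44.8), and with peaks at FDR 0.05 the counts were 12 (84.7) and 7 (40.8).

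Genes of progenitors and of other brain regions differed from list to list. The promoters of 9 of 10 neural progenitor genes were open (96.5), including the Notch effector genes Hes1 (4.27 ± 0.238) and Hes5 (2.43 ± 0.533), Pax6 (2.91 ± 0.578) and Sox2 (2.15 ± 0.481), and Eomes, a marker of intermediate progenitors, was the exception. The striatal list also had 9 of 10 open (96.6), with Rgs9 at 4.34 ± 1.37, Ppp1r1b at 1.89 ± 0.0738 and the dopamine receptor gene Drd1 at 1.64 ± 0.342. Cerebellar genes were open at 3 of 12, Cbln1 (3.59 ± 0.963), Cbln3 (1.83 ± 0.0649) and Zic2 (1.02 ± 0.127), at percentile 0.680, and Barhl1, En1, Gabra6 and Pax2 had none. Monoaminergic genes were open at 4 of 11 (4.92), with Nr4a2 at 1.51 ± 0.127, the serotonin synthesis gene Tph2 at 1.41 ± 0.534, Foxa1 at 0.748 ± 0.445 and Slc6a4 at 0.604 ± 0.0507, and none at Fev, Foxa2, Lmx1a and Lmx1b. The thalamic and hypothalamic list had 4 of 12 open (2.56), with the neuropeptide genes Agrp (4.01 ± 0.446) and Hcrt (2.32 ± 0.504), Tcf7l2 (1.55 ± 0.380) and Sim1 (1.51 ± 0.206), and none at Avp, Gbx2, Nkx2-1 and Otp. The cerebellar call was lost within 2 kb of a start (6.41) and with peaks at FDR 0.05 (11.9), where the progenitor and striatal lists passed the upper limit (99.1 each, with 10 of 10 open in both, Eomes included), as the striatal list also did in replicate 1 alone (10 of 10, 99.45), while in the higher 50% of peaks it had 6 of 10 open (55.6). Against CpG-matched lists the monoaminergic percentile was 0.025 and the thalamic and hypothalamic percentile 0.005, both below the limit, as they also were within 500 bp of a start (0.3 and 0.875), and the progenitor percentile was 43.2. Monoaminergic genes were also below it in the higher 50% of peaks (0.52), and thalamic and hypothalamic genes in replicate 2 alone (4 of 12, 1.44) but not in replicate 1 alone (6 of 12, 18.4).

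Markers of organs outside the brain had few open promoters. No gene of the retina (0 of 9), lymphocyte (0 of 11), pancreas (0 of 9) or Hox (0 of 35) lists had a promoter peak in both libraries, at percentiles of 0.005, 0, 0.015 and 0. The genes named by rule without a peak in either library were Arr3, Crx, Gnat1 and Nrl for retina, Cd3d, Cd3e and Cd3g for lymphocytes, Cela1, Cpa1, Gcg and Ins1 for pancreas, and Hoxa5, Hoxa9, Hoxa11 and Hoxa13. Of the Hox genes 3 had a promoter peak in replicate 1, 8 in replicate 2 and 24 in neither. In 5 further lists 1 gene was open: Apob of 14 hepatocyte genes (1.52 ± 0.730, percentile 0), the alpha-actinin gene Actn3 of 11 skeletal muscle genes (5.46 ± 0.347, percentile 0.005), Nppa of 10 heart genes (0.964 ± 0.196, percentile 0.035), the stem cell gene Lgr5 of 9 intestinal genes (0.993 ± 0.390, percentile 0.155) and Dazl of 9 germ line genes (2.19 ± 0.407, percentile 0.13). Within 500 bp of a start 0 hepatocyte and 0 skeletal muscle genes were open. Neither Apob nor Actn3 therefore had a peak that near a start in both libraries. In 1 library alone 2 genes were open for hepatocytes (replicate 1), skeletal muscle and germ line (replicate 2) and 1 for pancreas (replicate 1), and with peaks at FDR 0.05 the counts were 9 for Hox genes, 3 for skeletal muscle and germ line, 2 for lymphocytes and intestine and 1 for pancreas, all at percentiles below the lower limit. Without a peak in either library were Ahsg, Alb, Apoa2 and Cps1 of liver, Acta1, Ckm, Mb and Myf5 of skeletal muscle, Gata4, Hand2, Myh6 and Myl2 of heart, Cdx1, Cdx2, Fabp2 and Lct of intestine, and Acr, Ddx4, Mael and Prm1 of the germ line. Keratinocyte genes were open at 3 of 10 (2.46), Krt10 (3.37 ± 0.605), Grhl3 (0.516 ± 0.0451) and Trp63 (0.464 ± 0.0923), with none at Dsg3, Ivl, Krt1 and Krt14. Erythroid genes were open at 3 of 10 (2.72), among them Epor (1.87 ± 0.393) and Tal1 (0.618 ± 0.0282), with none at Alas2, Gata1, Hba-a1 and Hbb-bs. The keratinocyte call was lost without replicate 1 (5.59), with peaks at FDR 0.05 (4.50), without dense runs of low peaks (2.51; at least 10 peaks of height below 0.3 within 25 kb, a set defined after the data were seen) and against CpG-matched lists (30.6). Erythroid genes were below the limit in either library alone (2.22 for replicate 1, 1.56 for replicate 2), with peaks at FDR 0.05 (1.16) and in the higher 50% of peaks (0.135), and at 47.2 against CpG-matched lists.

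**Figure D1:**
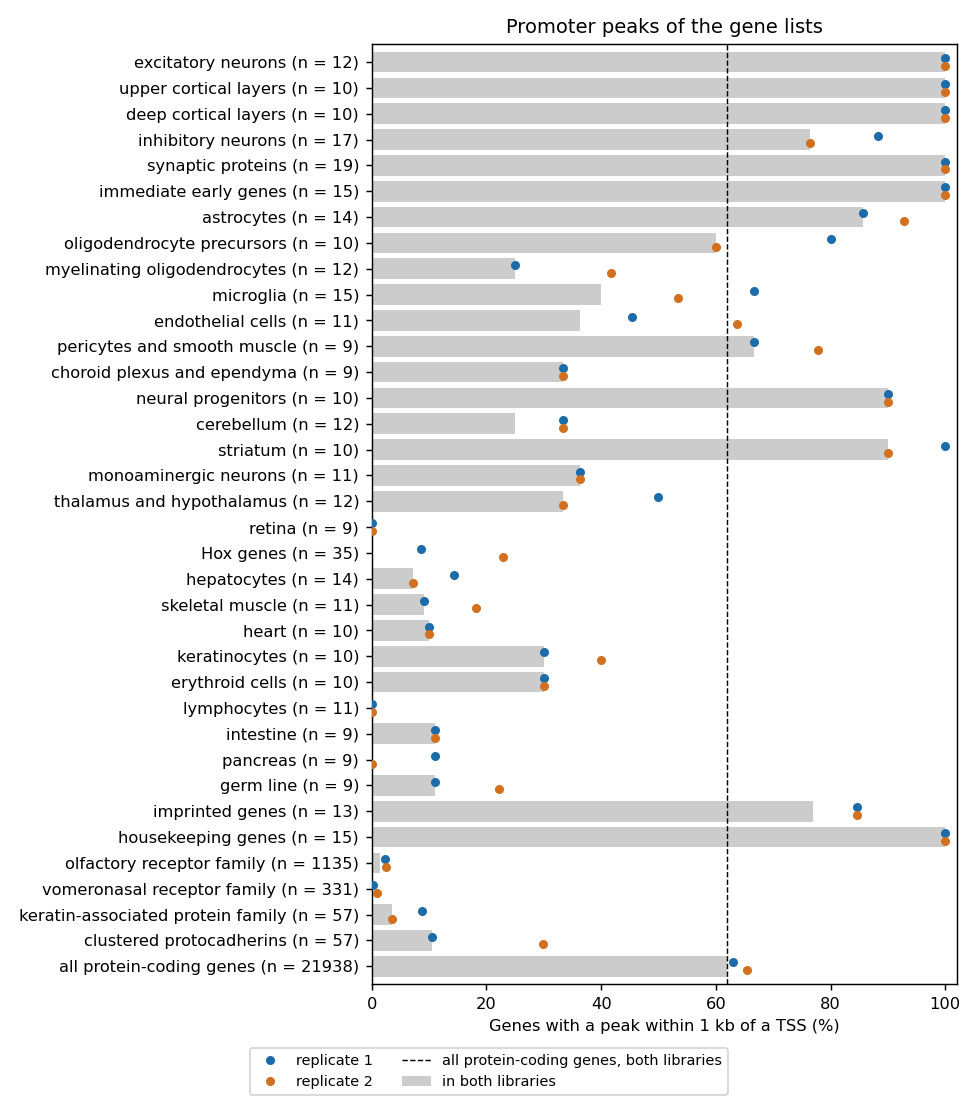
Percent of the genes of each list with a peak within 1 kb of a transcription start (TSS), in each library (points) and in both (bars), with n genes per list and a dashed line at the 61.9% of all protein-coding genes. The synaptic, immediate early, excitatory, upper-layer, deep-layer and housekeeping lists reach 100%, and the retina, Hox, lymphocyte and pancreas lists are at 0 in both libraries together.

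Of 13 imprinted genes 10 were open (86.2), among them Peg3 (6.18 ± 0.461), Kcnq1ot1 (4.74 ± 1.89), Snrpn (2.55 ± 0.270) and Peg10 (1.94 ± 0.810), with none at Ndn. Against CpG-matched lists the percentile was 98.2. Few members of large gene clusters were open. Promoter peaks in both libraries were found at 17 of 1135 olfactory receptor genes, 1 of 331 vomeronasal receptor genes, 2 of 57 keratin-associated protein genes and 6 of 57 clustered protocadherin genes, each at percentile 0. In replicate 1 and replicate 2 alone the counts were 26 and 29 olfactory receptor genes, 1 and 3 vomeronasal receptor genes, and 5 and 2 keratin-associated protein genes. The protocadherins, adhesion proteins expressed in neurons, had 6 promoters open in replicate 1 and 17 in replicate 2. Members of such families are similar in sequence, and the share of them that could be mapped uniquely was not measured.

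Distal peaks, those more than 1 kb from any annotated start, were denser than around random genes for 8 of the 31 lists, among them excitatory neurons, immediate early genes and astrocytes. The excitatory neuron list had a median of 16.2 peaks per 100 kb of locus, against 3.45 for random lists matched on locus length (percentile 99.99), and medians of 21.6 and 20.1 in replicate 1 and replicate 2 alone, of which that of replicate 1 was 12.2 without dense runs of low peaks. At Neurod2, 51.6 ± 20.4 peaks per 100 kb were counted, and at Camk2a 17.6 ± 7.71. Immediate early genes had a median of 13.6 against 2.37 and lay above each of the 10000 random lists, with 43.7 ± 16.9 at Egr1. Astrocyte genes followed with 10.3 against 3.33 (99.9), including 20.8 ± 4.21 at Gfap, whose promoter had a peak only at FDR 0.05. Neural progenitors had 9.11 against 2.09 (99.1; 5.63 in replicate 1 alone and 11.3 in replicate 2 alone), oligodendrocyte precursors 8.60 against 3.05 (98.6), microglia 7.47 against 3.23 (98.1), synaptic genes 7.44 against 3.70 (99.7) and upper layers 7.37 against 3.56 (97.9). All 8 lists were past the upper limit, and 0 of the 31 lists were past the lower one. With an extension of 50 kb the medians were 10.01 against 4.11 for excitatory neurons, 9.13 against 3.71 for immediate early genes, 8.05 against 3.37 for progenitors and 7.88 against 3.98 for astrocytes.

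The other lists lay within the limits. Thalamic and hypothalamic genes had a median of 7.09 per 100 kb (percentile 97.2), housekeeping genes 6.50 (96.05), myelinating oligodendrocytes 6.43 (93.2), cerebellum 6.22 (93.9), imprinted genes 6.02 (93.2) and inhibitory neurons 5.71 (93.01). Lymphocytes had 4.86 (79.96), deep layers 4.41 (69.1), retina 4.38 (70.7), heart 4.29 (73.4), pericytes 4.28 (71.4), monoaminergic neurons 3.96 (61.4), intestine 3.78 (55.3), striatum 3.61 (55.3) and Hox genes 3.57 (73.2). Hepatocytes had 3.08 (48.6), endothelium 3.05 (37.5), skeletal muscle 2.63 (43.1), pancreas 2.29 (43.9), keratinocytes 2.24 (34.4), choroid plexus 1.54 (14.2), erythroid cells 0.669 (14.9) and the germ line 0 (3.85). The synaptic call was lost in the higher 50% of peaks (65.6) and without dense runs of low peaks (85.5), and the calls for upper layers (92.6) and progenitors (95.7) were lost without replicate 2. Oligodendrocyte precursors fell inside the limits without replicate 1 (95.1), with peaks at FDR 0.05 (94.01) and without the extension of the gene body (95.7), upper layers without the extension (97.1), and microglia with an extension of 50 kb (90.9). Thalamic and hypothalamic genes passed the upper limit in the higher 50% of peaks (99.65), without the extension (99.6), without dense runs (98.3) and without replicate 1 (98.55), inhibitory neurons with peaks at FDR 0.05 (98.8), cerebellum without the extension (99.8), myelinating oligodendrocytes with an extension of 50 kb (98.35) and in the higher 50% of peaks (97.9), and imprinted genes in the latter (97.9). The intestinal median lay above those of each library alone, 1.57 in replicate 1 (16.8) and 1.27 in replicate 2 (6.38), and was 1.27 (6.21) without dense runs. Between replicate 1 and replicate 2 alone the median was 3.95 and 4.06 for cerebellum, 2.61 and 4.29 for heart, 0.814 and 4.004 for keratinocytes, 3.08 and 0 for choroid plexus, 0 and 1.34 for erythroid cells and 0 and 2.03 for pancreas.

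**Figure D2:**
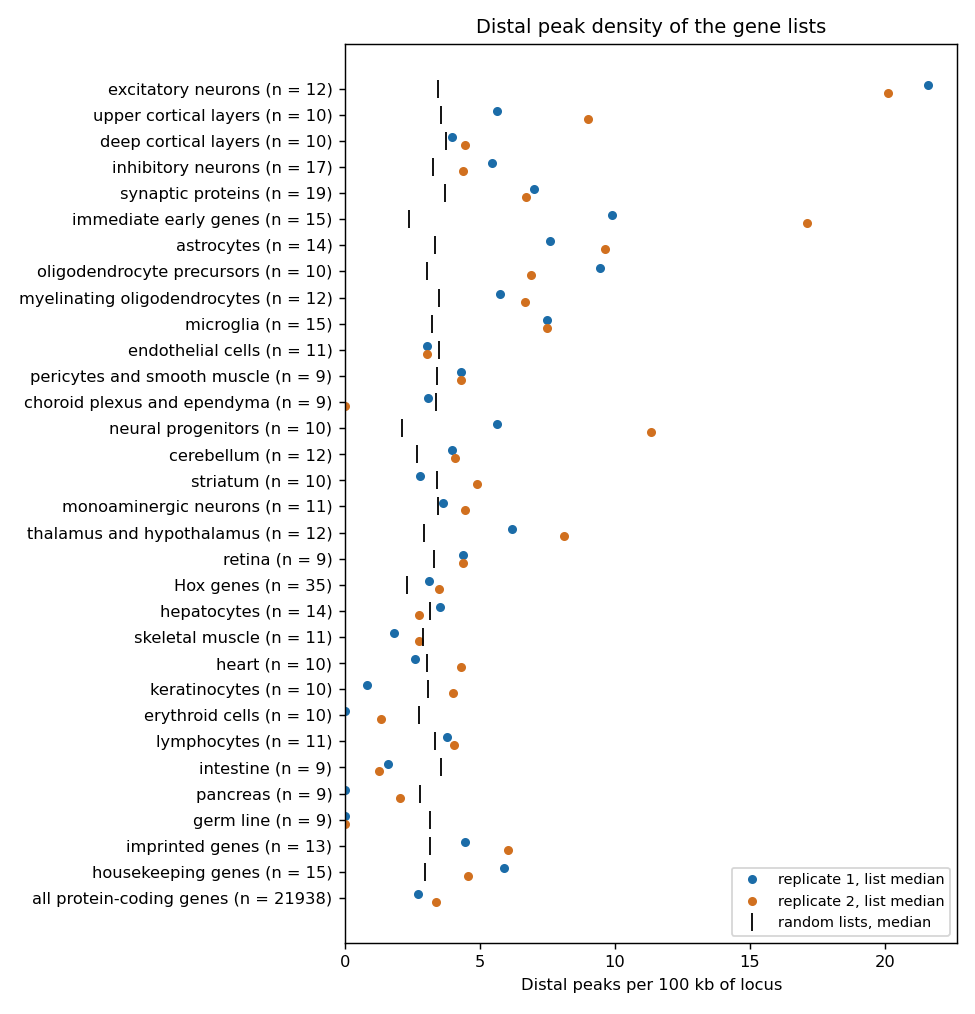
Distal peaks per 100 kb of locus as the median over each gene list in each library (points), with the median of random lists matched on locus length (vertical marks). The excitatory neuron list, at 21.6 in replicate 1 and 20.1 in replicate 2, and the immediate early genes, at 9.87 and 17.1, lie above their random lists, at 3.45 and 2.37, and without dense runs of low peaks the excitatory median of replicate 1 is 12.2.

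The gene with the most distal regions in both libraries was Gm20388, a gene model annotated on chromosome 8 from 119910841 to 124345722, with 232 regions. Others among the 10 genes with the most were the fibroblast growth factor receptor gene Fgfr2 (111), annotated on chromosome 7 from 130162451 to 133123350, the gene model Gm37240 (58), Ptprn2 (56), the Notch-related gene Dner (55), the basic helix-loop-helix gene Tcf4 (55), the axonal scaffold gene Ank3 (52), the synaptic scaffold gene Dlgap2 (49) and 4930556J24Rik (47). A region in overlapping genes counted for each of them, and these counts were not corrected for locus length. Large dense runs of low peaks lay at Tcf4 (84 run peaks in replicate 1, where replicate 2 had 48 peaks) and at Dlgap2 (93 run peaks in replicate 2, where replicate 1 had 78 peaks). The share of the counts that came from such runs was not determined.

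Some promoters were open in 1 library alone. Replicate 1 had 258 such protein-coding genes with a median height of 0.394, led by Gm17402 (4.12), Mst1 (2.87), the transcription factor gene Gata3 (1.29), Zfp957 (1.27) and the histone gene Hist1h3d (1.24). Replicate 2 had 765 with a median height of 0.584, led by Elmo3 (2.14), Syt8 (2.02), Prss57 (1.98), Nmur1 (1.94) and 4933415A04Rik (1.88). Over all protein-coding genes 13838 had a promoter peak in replicate 1, 14345 in replicate 2 and 7335 in neither.

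The motif of CTCF, an architectural protein that binds insulators, was the most enriched in distal peaks among the motifs with a computed ratio. It was present within 75 bp of the centre of 4.02% of 96537 distal peaks in replicate 1 and 5.598% of 99793 in replicate 2, against 0.0245% and 0.0261% for permuted forms of the motif, a log2 ratio of 7.55 ± 0.28. The RFX motif was at 5.45 ± 0.09. The CAGATG E-box, which NEUROD and related neuronal factors bind, was present in 8.09% and 6.99% of distal peaks against 1.603% and 1.583%, a log2 ratio of 2.24 ± 0.14. The ZIC motif was present in 9.13% and 9.41%, at 2.00 ± 0.00.

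Ratios of at least 1.5-fold in both libraries were found for 16 of the 30 motifs. Beside those above they were SP and KLF (3.13 ± 0.08), NFI (2.61 ± 0.60), a family active in glia and neurons, NRF1 (2.36 ± 0.04), PU.1 (2.08 ± 0.09), the microglial and myeloid factor, the SOX dimer (2.02 ± 0.07), the POU octamer (1.65 ± 0.09), the CAGCTG E-box (1.53 ± 0.04), NF-Y (1.35 ± 0.12), FOX (1.28 ± 0.00), TEAD (0.89 ± 0.04), ROR (0.88 ± 0.03) and the activity-dependent factor AP-1 (0.72 ± 0.07). ETS (-0.88 ± 0.09) and GATA (-0.62 ± 0.01) were at least 1.5-fold below their permutations in both. Between these lay MEF2 (0.57 ± 0.10), HNF4 (0.51 ± 0.16), T-box (0.50 ± 0.11), YY1 (0.47 ± 0.14), SOX (0.30 ± 0.08), EGR (0.24 ± 0.10), CRE (-0.03 ± 0.18) and the homeodomain motif (-0.68 ± 0.17). For POU3F, REST, HNF1 and TP63 fewer than 5 permuted hits were expected and no ratio was computed. REST sites were nonetheless present, in 0.0116% and 0.0338% of distal peaks outside dense runs in replicates 1 and 2, against 0% permuted. In 1 library alone the 1.5-fold limit was also passed by MEF2 (0.64, replicate 1), HNF4 (0.62, replicate 2) and, below, the homeodomain motif (-0.81, replicate 2). Calls depended on the background. Against windows 500 bp to the side, EGR (2.44), CRE (1.61), ETS (0.70) and YY1 (0.68) were at least 1.5-fold higher in both libraries, the POU octamer (0.23), TEAD (0.19), ROR (-0.057) and FOX (-0.40) lost their calls, HNF4 (-0.29), T-box (-0.15) and SOX (-0.36) turned in sign, and CTCF was at 4.93, RFX at 3.27 and the CAGATG E-box at 0.95. Against permutations that kept the CpG steps of the motif, a control chosen after the data were seen, CRE (2.15), EGR (1.66), T-box (0.83) and ETS (0.70) were higher and the homeodomain motif (-1.14) lower, AP-1 (0.53), ROR (0.37) and GATA (-0.51) lost their calls, SOX was at -0.29, RFX at 3.47 and ZIC at 0.90. CRE (0.63) and MEF2 (1.13) were also called in the higher 50% of peaks, where ETS (-0.74) was not, and MEF2 in windows of 50 bp on each side and without dense runs (0.76 each).

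**Figure D3:**
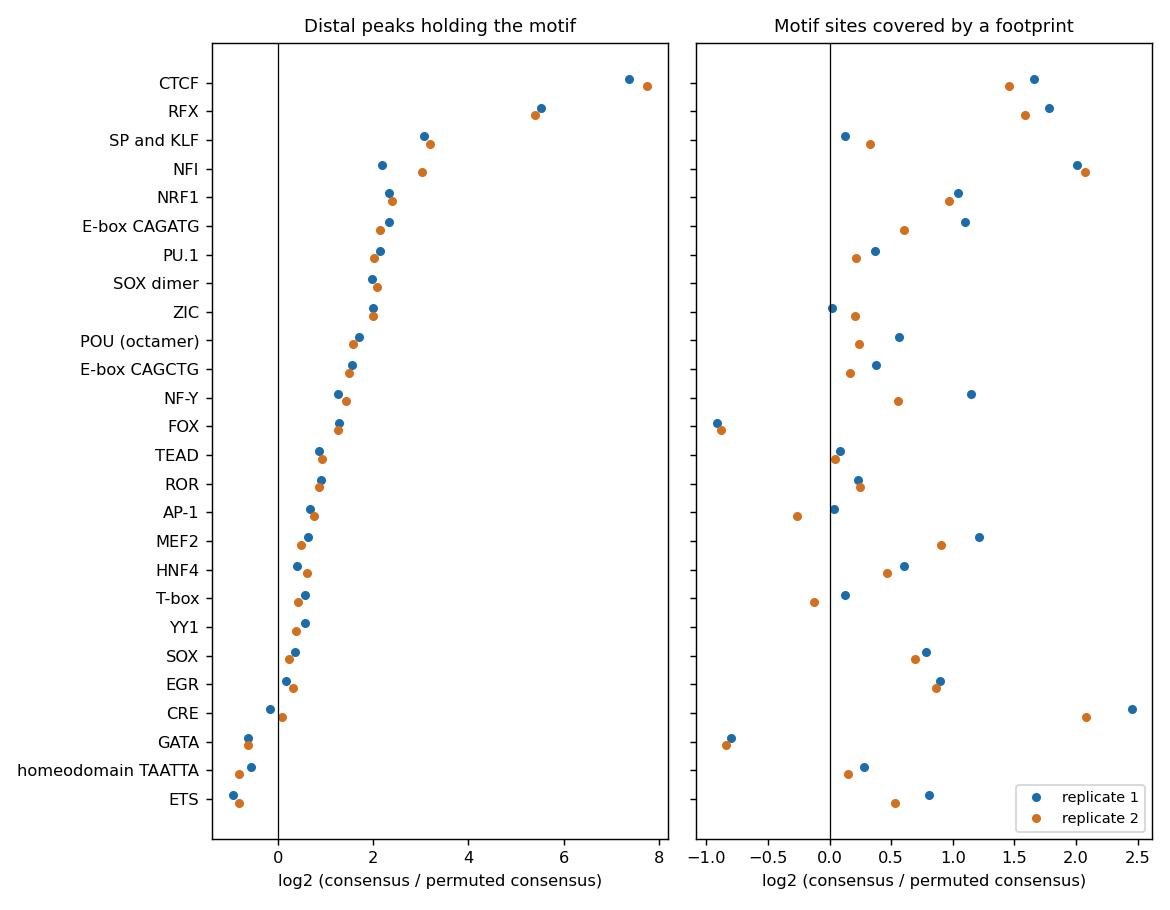
Log2 ratio of motif frequency in distal peaks over permuted motifs, and of footprint cover of motif sites over sites of permuted motifs, for each library (points). In peaks CTCF, with a mean of 7.55, and RFX, with 5.45, have the largest ratios, and in footprints CRE, with 2.27, and NFI, with 2.04.

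Footprints, short stretches protected from cutting inside accessible chromatin, covered nearly all CTCF and NFI sites over at least 50% of their length. Cover below is the share of sites covered to that extent. The files held 621203 footprints in replicate 1 and 600885 in replicate 2, with median widths of 10 and 11 bp and covering 8.05 and 8.25 Mb. Of these 57.3% and 60.9% touched a peak, and 86.0% and 86.6% of peaks had at least 1. Of the footprints inside peaks, 40.7% and 39.7% overlapped a footprint of the other library by at least 50% of their length, against 15.7% and 15.8% after moving footprints within the peaks. CTCF sites in distal peaks were covered at 96.98% and 97.91%, against 30.7% and 35.7% for permuted sites (log2 1.56 ± 0.15). NFI sites were covered at 97.35% and 99.04% (2.04 ± 0.05), RFX sites at 84.4% and 84.7% (1.68 ± 0.13) and sites of CRE, the element bound by CREB, at 73.1% and 70.0% (2.27 ± 0.26).

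Cover was also at least 1.5-fold above permuted sites in both libraries for MEF2 (1.06 ± 0.22), NRF1 (1.00 ± 0.05), EGR (0.88 ± 0.02), the CAGATG E-box (0.85 ± 0.35) and SOX (0.74 ± 0.07), which made 9 motifs. It was at least 1.5-fold lower for FOX (-0.90 ± 0.02) and GATA (-0.82 ± 0.03). NF-Y (0.85 ± 0.42), ETS (0.67 ± 0.20), HNF4 (0.53 ± 0.10), the POU octamer (0.40 ± 0.23), PU.1 (0.29 ± 0.11), the CAGCTG E-box (0.27 ± 0.15), ROR (0.24 ± 0.01), SP and KLF (0.23 ± 0.14), the homeodomain motif (0.22 ± 0.09), ZIC (0.11 ± 0.13), TEAD (0.06 ± 0.03), T-box (0.00 ± 0.18) and AP-1 (-0.12 ± 0.21) were between these. No ratio was computed for POU3F, REST, HNF1, TP63, YY1 and the SOX dimer, for which permuted sites were too few. In replicate 1 alone NF-Y (1.15), ETS (0.81) and HNF4 (0.60) passed the upper limit. With any overlap of 1 bp as cover, 0 motifs were at least 1.5-fold lower.

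The X chromosome, present in 1 copy in males, had fewer and lower peaks than any autosome. It held 2694 peaks in replicate 1 and 3152 in replicate 2, or 16.5 and 19.3 per Mb of known sequence, against 42.0 to 68.9 and 43.2 to 82.4 on the autosomes, where chromosome 3 was lowest and chromosome 11 highest in both. Relative to the median autosome the density was 0.328 ± 0.0204. The median height was 0.427 and 0.488 on the X chromosome against 0.511 to 0.714 and 0.657 to 0.823 on autosomes, a ratio of 0.696 ± 0.0429. The Y chromosome held 59 and 43 peaks. In the higher 50% of peaks the density ratio was 0.212. Among promoter peaks alone the density ratio was 0.498.

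**Figure D4:**
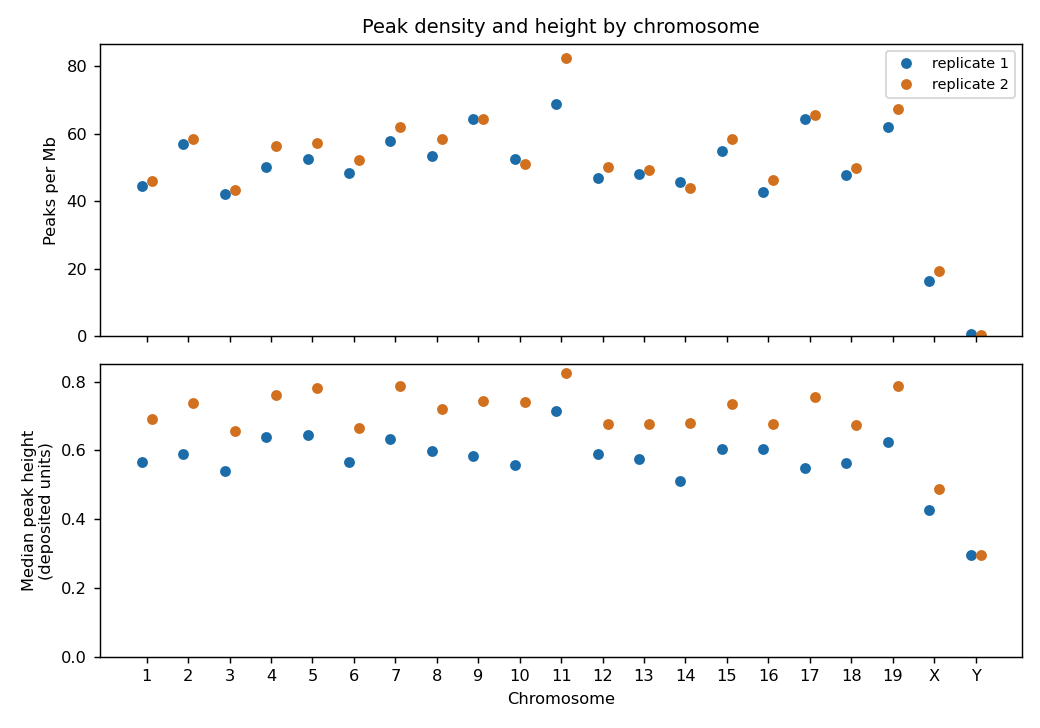
Peaks per Mb of known sequence (upper plot) and median peak height in deposited units (lower plot) of each chromosome, in each library (points). The X chromosome, at 16.5 and 19.3 peaks per Mb, lies below all autosomes, which start at 42.0 and 43.2.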

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

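The permutations that keep CpG steps and the peak sets without dense runs of low peaks were chosen after the data were seen, and the other alternatives before. Over 139 values and 19 alternatives, 933 comparisons were made. Of these 679 kept their call or stayed within the limit of their measure, 193 moved past that limit, 19 lost a call, 36 gained a call and 6 reversed in sign. The limit was the replicate SD for motif ratios and shares by location, and the Wilson interval for shares of shared peaks. For peak numbers and covered lengths it was 1.5-fold, and for the Spearman coefficient a small fixed difference. The 19 and 36 are calls of gene lists alone, and motif calls lost or gained were not counted there. Reversals were counted only where a motif lay at least 0.25 from 0 on the log2 scale, on the same side, in both libraries. No paired analysis was possible because the series has 1 group. Depth per library is unknown, so its effect on the number of peaks was not tested, and the causes of the shifts below were not tested except where the alternative itself sets them, as a peak threshold sets the number of peaks.

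With peaks at FDR 0.05 there were 219811 peaks over 44.7 Mb in replicate 1 and 239253 over 43.6 Mb in replicate 2, 66.9% of replicate 1 peaks were shared, the lists above random at promoters went from 6 to 10, and 1 list, the germ line (2.11), fell below random in distal density. In the higher 50% of peaks the number of peaks, replicate 1, was 64206 over 14.4 Mb and the number of peaks, replicate 2, was 68073 over 13.9 Mb, with 36.1% at promoters, 4.49% in exons, 33.9% in introns and 25.5% between genes, X density and height ratios of 0.212 and 1.03 (this set is chosen by height, which brings the medians of all chromosomes together, so its height ratio does not test the lower heights on the X chromosome), and 1 motif instead of 2 lower in distal peaks and 1 instead of 2 in footprints. With promoters within 500 bp the shares were 18.2%, 6.84%, 41.8% and 33.1% for promoter, exon, intron and intergenic, and within 2 kb they were 30.8%, 4.57%, 34.6% and 30.02%. Without dense runs of low peaks they were 27.6%, 5.55%, 36.3% and 30.6%, with 73.3% and 66.2% of peaks shared and X density and height ratios of 0.377 and 0.618. Promoter peaks alone gave X ratios of 0.498 and 0.609, and distal peaks alone a density ratio of 0.278.

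Sharing was 54.8% and 51.7% when at least 50% of both peaks had to overlap, and 78.3% and 78.9% among the 63952 highest peaks of each library. With any overlap of 1 bp, 47.0% and 46.3% of footprints inside peaks were shared and 0 motifs were lower in footprints, and with full cover 1 motif was. Flanking windows at 500 bp reversed ETS (0.70), FOX (-0.40), HNF4 (-0.29), T-box (-0.15) and ROR (-0.057), took SOX (0.30 to -0.36) and CRE (-0.03 to 1.61), both too near 0 to be counted, across 0, and left 1 motif, GATA (-0.85), lower in distal peaks. Permutations keeping CpG steps reversed ETS (0.70), took SOX to -0.29 and CRE to 2.15, and brought GATA inside the limit (-0.51), and the 1 motif lower there was the homeodomain motif (-1.14).

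Against CpG-matched lists 11 of the 12 lists below random stayed below, and 4 of the 6 above stayed above, while 3 lists joined below and 2 above. With n = 2 a single library lies within 1 SD of a mean over both by construction, so for such means leaving out a library tests nothing, and those comparisons among the 679 say nothing about stability. Counts of calls, which could have changed, stayed within 1.5 times. Leaving out a library changed 7 calls of single lists without replicate 1 and 5 without replicate 2, and 6 motif ratios between the limits, 3 in peaks and 3 in footprints, passed one in 1 library alone.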

Other observations

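The 25 further gene families, the dense runs and the comparison of CTCF regions between replicates were chosen after the main results were seen, and the test on the X chromosome was written before its result was seen. Ionotropic glutamate receptor genes had a promoter peak in both libraries at 16 of 18 members (percentile 99.3 among random lists), with Gria2 at a height of 4.52 ± 0.230 and no peak at Grin2c and Grin3b. Potassium channel genes were open at 67 of 92 (98.6), led by the subunit gene Kcnab2 (13.7 ± 0.0813), and semaphorins at 17 of 20 (98.5), led by Sema4b (6.53 ± 0.706). Against CpG-matched lists these fell inside the limits, at 85.5, 82.9 and 75.6. GABA-A receptor subunits were open at 13 of 19 (71.3), with Gabrg1 at 2.82 ± 0.508 and none at Gabra6, Gabrp, Gabrr1, Gabrr2 and Gabrr3. Voltage-gated calcium channels (20 of 25, 97.01), sodium channels (8 of 14, 35.8), metabotropic glutamate receptors (6 of 8, 75.4), serotonin receptors (9 of 14, 55.7), fibroblast growth factors (16 of 22, 84.8), Eph receptors and ephrins (18 of 22, 97.4) and solute carriers (212 of 340, 56.3) lay inside the limits, but solute carriers were below the lower limit against CpG-matched lists (0.735). Nicotinic acetylcholine receptors were open at 4 of 16 (0.2), led by Chrnb1 (4.89 ± 0.0884). Wnt ligands were open at 9 of 19 (10.2), and against CpG-matched lists at percentile 0.005.

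Of the families past the upper limit, 4 were past it against CpG-matched lists as well, with 36 of 36 complex I genes of the Nduf family, 37 of 39 proteasome genes, 73 of 76 ribosomal protein genes and 316 of 365 zinc finger genes named Zfp. All were at percentile 100 among unmatched random lists, and in this order at 99.5, 99.7, 99.9 and 100 against CpG-matched lists. Type I interferons (0 of 18), beta-defensins (0 of 42), kallikreins (0 of 26), keratins (4 of 49), taste receptors (1 of 38), interleukins (8 of 33), serpins (9 of 61) and cytochrome P450 genes (24 of 93) were each at percentile 0. The highest promoters of the last 2 families were those of Serpini1, which encodes neuroserpin (11.8 ± 0.743), and Cyp46a1, the cholesterol 24-hydroxylase of neurons (14.5 ± 0.0249). Against CpG-matched lists taste receptors (4.33), interleukins (10.3), serpins (10.5) and cytochrome P450 genes (17.9) were inside the limits. By gene type, 20.8% of 5854 lincRNA genes, 36.4% of 2959 antisense genes and 14.9% of 2202 miRNA genes had a promoter peak in both libraries, against 61.9% of protein-coding genes and 3.13% of 9940 processed pseudogenes.

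Peaks on the X chromosome were lower than on autosomes. Shared distal regions with a CTCF motif, a site class bound in most cell types, had a median height ratio of X to autosomes of 0.486 in replicate 1 (bootstrap 95% range 0.434 to 0.567) and 0.460 in replicate 2 (0.407 to 0.536), over 99 regions on the X chromosome and 3691 on autosomes. The medians of single autosomes were 0.855 to 1.07 and 1.85 to 2.19, against 0.484 and 0.936 on the X chromosome. These ratios are consistent with 1 copy of the X chromosome in male animals as a candidate explanation of the lower heights. Allele-specific mapping and mappability of the X chromosome stay open and were not tested, and the low density of peaks may include peaks lost below the calling threshold.

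Low peaks formed dense runs that lay mostly in 1 library, with 899 runs holding 15.5% of peaks in replicate 1 and 608 holding 10.8% in replicate 2, of which 26.6% and 39.1% met a run of the other library, against 1.15% and 1.77% after 100 circular shifts (a run had at least 10 peaks of height below 0.3 within 25 kb). Of 23 genes of the lists with run peaks, 17 had them in replicate 1 alone and 3 in replicate 2 alone, and at genes chosen after their values were seen they numbered 43 and 0 at Grin2b, 41 and 0 at Slc4a4, 29 and 16 at Gria1 and 14 and 14 at Grin2a in replicates 1 and 2, while the largest run of replicate 1 held 91 peaks at Lpar3 on chromosome 3 from 146276341 to 146383220, where replicate 2 had 61 peaks. Higher cleavage over the whole stretch was tested on shared regions of height at least 0.3 inside runs. Their log2 ratio of that library to the other exceeded the ratio elsewhere by 0.0165 for replicate 1 (bootstrap -0.01 to 0.04). For replicate 2 the excess was -0.0196 (-0.04 to 0.01), and both were below the 0.25 set beforehand. Run peaks had median heights of 0.1255 in replicate 1 and 0.1295 in replicate 2, below the 0.3 required of the tested regions. Added cleavage of that size may shift the ratio of higher regions by less than 0.25, so the test cannot decide on this explanation. Clusters of regulatory elements cannot be told apart from other sources. The CAGATG E-box kept 63.2% and 59.9% of its log2 enrichment elsewhere (4.71% and 4.43% of run peaks against 1.67% and 1.66% permuted). Its ratio over all distal peaks was smaller against flanking windows than against permutations. Part of its enrichment over permutations is thus shared by sequence beside the peaks, and the share kept cannot decide. CTCF, in 0.148% and 0.1004% of run peaks against 4.96% and 6.49% elsewhere, had too few permuted hits for a ratio. Other motifs went both ways. In replicate 1 log2 ratios in runs and elsewhere were -0.70 and 0.87 for MEF2 and 0.97 and 0.44 for T-box. In runs the 5th percentile of peak height was 0.0568 in replicate 1 and 0.0598 in replicate 2, against 0.182 and 0.249 for other peaks. Runs were defined by low height, and whether the calling limit was lower there was not tested. A difference between the animals was not tested either, since the design has 1 group, and stays open.

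CTCF regions were higher in replicate 2 than in replicate 1 beyond the general shift. Over 3790 shared distal regions with the motif the median log2 height ratio of replicate 2 to replicate 1 was 0.98, against 0.18 over 51601 others, and 98.6% of them were higher in replicate 2 against 63.0%, while the median was 0.55 for the 99 NFI regions, 0.35 each for ZIC, ETS, CRE and SP and KLF regions, 0.03 for CAGATG E-box regions and 0.00 for RFX regions. Against regions matched on GC content 101% of the excess was left (0.81, range 0.78 to 0.85 over 200 draws). Against regions matched on width 88.2% was left (0.71, range 0.67 to 0.75). Before matching, median GC content was already close, at 50.99% in CTCF regions and 52.32% in the others. Median widths were 174.5 and 182.5 bp. Matching thus had little to remove and is a weak test of either cause. It shows only that these small differences between the groups did not account for the whole excess. Digestion level and fragment size of the libraries may contribute and were not tested. No biological explanation was tested, since the design has 1 group.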
